A study of Mus musculus with 4 samples.

How the data were processed

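Total RNA of whole mouse heart was measured on 1-colour oligonucleotide arrays, in 2 samples of wild-type mice and 2 samples of heterozygous mice. The gene in which they were heterozygous is not reported here. Per the labels, the animals were adult males aged 8 to 16 weeks on a 129/Black Swiss background, every sample was RNA of a pool of 5 hearts, and RNA was isolated with Trizol and an additional phenol-chloroform step. The labels number the pools 1 and 2 within each genotype and do not say that the pools were drawn from separate animals, so the p-values here measure only the spread between these 4 samples. Pools of 5 hearts also vary less than single animals do.

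The values the authors deposited are linear signal intensities, 1 per probe set and array, with no log taken. The software that summarised probes into probe sets is not given in the sources used here. The deposited intensities had nearly the same trimmed mean on every array: with 2% removed at each end, it was 1501.07 and 1501.02 in the wild-type pools and 1501.19 and 1486.94 in the heterozygous pools. The highest was 1.01 times the lowest, under the limit of 1.05 set for treating the table as already scaled, so the intensities were used as deposited. Heterozygous pool 2 carried no value for the 66 control probe sets, which accounts for its lower trimmed mean: without controls, the trimmed means ran from 1486.5 to 1488.07. Signals are therefore relative to the total of each array, and a large change in some transcripts moves all others the opposite way.

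Signals below the 10th percentile of all values (36.25) were raised to it, and log2 was taken. This floor touched 16 of the 29812 values of tested probe sets. The 66 controls were removed from the 12488 probe sets, and the 40% of the remaining 12422 with the lowest mean over all arrays were not tested, which left 7453 tested and 4969 untested. Each tested probe set was fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, with genotype as the only term, and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are heterozygous minus wild type, errors of log2 changes are limma's standard errors (SE), and errors of signals are standard deviations (SD) over 2 pools. An exact permutation test of 2 pools against 2 cannot give a two-sided p below 0.333.

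Gene lists were tested with camera in limma, with a preset correlation of 0.01, on the probe set with the highest mean signal of every gene. Of 31 lists, 29 had at least 5 tested genes and were adjusted together. For these 29 lists, counts of changed genes are given over all tested probe sets and, beside them, adjusted over the list alone. Lists drawn up later have only the count over all tested probe sets. The same test with a correlation estimated from the data has 2 residual degrees of freedom here, and none of the lists passed with it.

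Probe sets were named through the platform annotation: 10855 carried 1 gene symbol, 396 carried several and 1237 carried none, and only those with 1 symbol were named. By gene ID, 10839 of the symbols were found among the mouse genes of GRCm38.p6 and 0 symbols changed. The named probe sets covered 8251 genes, of which 5692 were tested. No genome build goes with these values, so no coordinates are given.

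The groups, the test, the gene lists, the rule for named genes and most of the other ways of analysis were fixed before the data were examined. Named genes are the members of the sodium pump list and 9 heart genes chosen in advance (Pln among them was not analysed here), the 10 largest increases and 10 largest decreases among probe sets past the threshold whose pools did not overlap between genotypes, the 4 members with the smallest p in the direction of each list that passed, and up to 4 changed members of every other list. These other ways were other scalings between arrays, other floors, other filters on dim probe sets, other moderation of the spread, the pool number as a block, each pool left out in turn, other thresholds and other set tests. A scaling to a common mean of the sarcomere genes was added after the data were seen.

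The fit was tested on simulated data with known changes for the same 7453 probe sets. It recovered 22.4% of 1.5-fold changes, 68.7% of 2-fold changes and 93.9% of 4-fold changes, and 10.2% of its calls were false. Only 67, 67 and 66 probe sets were changed at these folds, with noise drawn independently. In the real data 38.3% of probe sets were called. Both rates depend on that share, so they do not carry over to the real comparison. The simulated list with a shift passed the set test, and 0 of 28 lists without one did. These lists held random genes with independent noise, so they do not show how camera acts on genes that vary together. For arrays, the number of samples limits the precision. Plots were drawn with matplotlib.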

Results

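Hearts of wild-type and of heterozygous mice were compared on 4 arrays of 12488 probe sets. Every genotype was represented by 2 pools of 5 hearts. The comparison asks which transcripts of the heart differ in level between the genotypes. Median signals were 569.6 and 608.55 in the wild-type pools and 508.85 and 531.15 in the heterozygous pools. Log2 signals of tested probe sets correlated at 0.971 between the wild-type pools, at 0.970 between the heterozygous pools and at 0.845 to 0.856 between pools of different genotype, as correlations across probe sets, which are not independent replicates. The median absolute log2 difference was 0.21 within either genotype and 0.46 between the genotype means.

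Among regulators of Na,K-ATPase, the pump that exchanges sodium inside the cell for potassium outside, Fxyd1 (phospholemman, its regulator in heart) rose 2.23-fold in the heterozygous pools, from a signal of 12059 ± 3086 to 26481 ± 150 (SD, n = 2; log2 change 1.16, SE 0.18, adjusted p = 0.00127). Fxyd2, the gamma subunit best known from kidney, fell 2.99-fold (log2 change -1.58, SE 0.24, adjusted p = 0.00119) and Fxyd5 fell 2.24-fold (log2 change -1.16, SE 0.22, adjusted p = 0.00320). Fxyd3 fell 2.18-fold (log2 change -1.13, SE 0.30, adjusted p = 0.0178). The log2 changes of the beta subunits Atp1b3 (-0.27, SE 0.14, adjusted p = 0.163) and Atp1b1 (0.07, SE 0.23, adjusted p = 0.846) did not pass, although Atp1b3 passed as lower under quantile normalization (-0.39) and cyclic loess (-0.47). Of the 6 tested members of this list, 1 rose, 3 fell and 2 did not pass, also when adjusted over the list alone. The list did not pass camera, which compares it with other genes (adjusted p = 0.227, and adjusted p = 0.372 with an estimated correlation), but passed as lower with fry, which does not (adjusted p = 0.00456; range across alternatives 0.00456 to 0.640). Over the same pools, markers of lymphocyte and thymus had a median log2 change of -2.42. The 4 FXYD calls ended when dim probe sets were not filtered out. The Fxyd3 call also ended without wild-type pool 1, wild-type pool 2 or heterozygous pool 1 (log2 changes of -1.27, -0.99 and -1.07).

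Of 7453 tested probe sets, 2856 (38.3%) differed between the genotypes, 1337 of them higher and 1519 lower in the heterozygous pools. The larger changes were mostly decreases: 382 probe sets rose and 874 fell at least 2-fold, and 17 rose and 275 fell at least 4-fold. The pools of the genotypes did not overlap in 70.1% of tested probe sets, where chance alone gives 33.3%. With arrays shifted to a common median, the median log2 change of all tested probe sets moved from 0.00 to 0.18 (0.10 under quantile normalization). Higher calls made up 62.5% of the calls with the common median, in place of 46.8%. Without the filter on dim probe sets, the calls numbered 1206 (482 higher, 724 lower). With arrays centred on the sarcomere list they numbered 4351 (171 higher, 4180 lower). Without heterozygous pool 1 the number of higher calls was 660, and without heterozygous pool 2 it was 653.

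**Figure D1:**
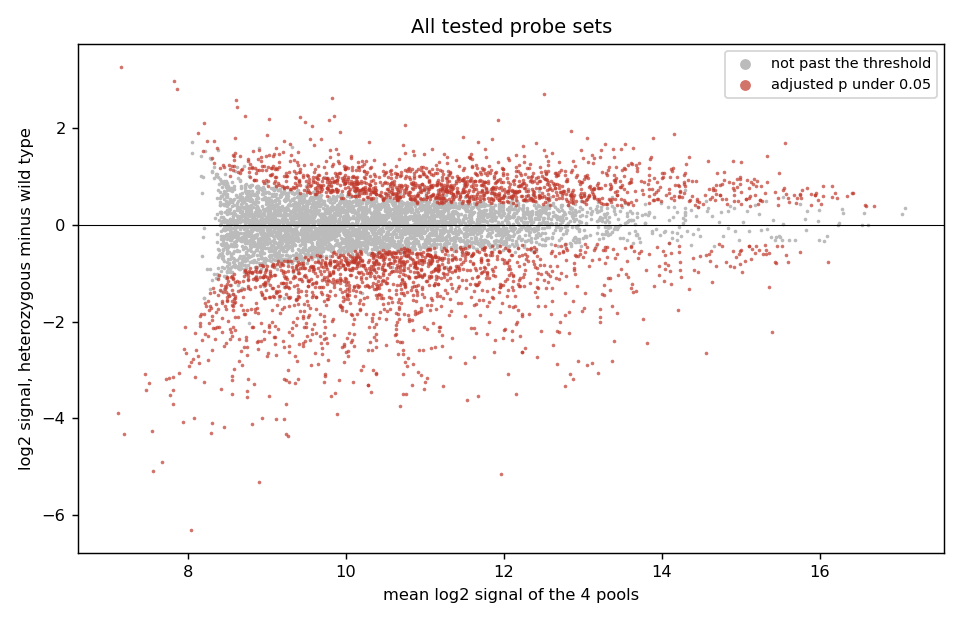
Log2 change (heterozygous minus wild type, vertical axis) against the mean log2 signal of the 4 pools (horizontal axis) for the 7453 tested probe sets, 1 point each, with the 2856 past an adjusted p of 0.05 in red; signals on the horizontal axis are drawn without the floor. Decreases reach further from 0 than increases: 275 probe sets fell and 17 rose at least 4-fold.

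The 10 largest increases included Dmpk, the kinase gene of myotonic dystrophy, whose signal rose 6.60-fold from 2270 ± 199 to 14967 ± 614 (SD, n = 2; log2 change 2.72, SE 0.15, adjusted p = 8.6e-06). Its neighbour Six5, a homeobox gene, rose as well (log2 change 2.81, SE 0.56; 3.41 without wild-type pool 1 and 2.21 without wild-type pool 2). Kcnk3, which encodes a background potassium channel, rose 6.18-fold (log2 change 2.63, SE 0.21). Nos3, the endothelial nitric oxide synthase, rose 6.04-fold, and Flt1, a receptor of vascular endothelial growth factor, rose 4.50-fold on 1 probe set and 2.31-fold on another. Itga5, an integrin subunit, rose from a signal near the floor in wild-type pool 1 (36.6; 179.3 in pool 2), so its log2 change of 2.98 (SE 0.73) was 1.83 without wild-type pool 1 and 4.12 without wild-type pool 2. Tinagl1 rose 4.56-fold. Sftpc, the surfactant protein C gene of lung, rose 4.76-fold. The pyruvate kinase gene Pklr differed widely between the wild-type pools (58.4 and 488.2). Its log2 change of 2.45 (SE 0.79) was 0.92 without wild-type pool 1 and 3.98 without wild-type pool 2, and its call ended without heterozygous pool 1 (2.52) or heterozygous pool 2 (2.39). Pola2, a subunit of DNA polymerase alpha, had probe sets that disagreed, with log2 changes of 2.25 and -1.17. The calls of Itga5, Six5, Pklr, Pola2 and Flt1 (the larger change) ended without the filter on dim probe sets.

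The 10 largest decreases included genes of lymphocytes. Cd8b1, the beta chain of the T cell coreceptor CD8, fell 35.8-fold, from a signal of 24157 ± 4327 to 675.9 ± 133 (SD, n = 2; log2 change -5.16, SE 0.19, adjusted p = 7.3e-06). Sla, an adaptor that dampens T cell receptor signalling, fell 20.2-fold, and Arhgap9, of blood cells, fell 16.0-fold on 1 probe set and less on a brighter one (log2 change -2.54). Vav1, an exchange factor of blood cells, fell on 2 of 3 tested probe sets (log2 change -1.64 on 1 and -4.13 on the other, SE 0.66; -5.36 without heterozygous pool 1 and -2.90 without heterozygous pool 2), while the dimmest had a log2 change of 0.82 (adjusted p = 0.152). The antigen receptor genes Ighm (at least 30.2-fold on the probe set with the largest change, log2 change -1.09 on the brightest), Ighg3 and Trbv1 fell as well. On the probe sets with the largest change, Ighg3 had a log2 change of -4.28 (SE 0.54; -3.67 without heterozygous pool 1 and -4.91 without heterozygous pool 2), and Trbv1 had one of -4.01 (SE 0.44; -3.26 and -4.76), against -2.65 on its brighter probe set. Ighm and Ighg3 had 1 heterozygous value each raised to the floor, so their decreases are lower bounds. Probes of such gene families can detect several members. Uhrf1, which maintains DNA methylation in dividing cells, fell 15.1-fold, Nsg2 fell 20.6-fold and the keratin gene Krt17 fell 19.7-fold. The calls of Vav1 and Trbv1 ended without the filter on dim probe sets.

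All 18 tested markers of lymphocyte and thymus fell, with a median log2 change of -2.42 (camera adjusted p = 5.7e-15, and adjusted p = 0.158 with an estimated correlation), and all 18 passed when adjusted over the list alone. Rag1, which cuts antigen receptor genes in developing lymphocytes, fell 8.44-fold from 27192 ± 2314 to 3217 ± 47.7 (SD, n = 2; log2 change -3.08, SE 0.14, adjusted p = 7.7e-06), although its other tested probe set had a log2 change of 0.61 (adjusted p = 0.0650). Cd8a fell 11.4-fold and Cd3d, a chain of the T cell receptor complex, fell 11.7-fold. The B cell gene Cd79a had the smallest change of the list, a log2 change of -0.59. The 20 tested cell cycle genes fell too, all 20 also when adjusted over the list alone, with a median log2 change of -2.49 (camera adjusted p = 8.5e-16, and adjusted p = 0.158 with an estimated correlation). Mki67, a marker of dividing cells, fell 10.5-fold. Rrm2, which makes deoxynucleotides, had a log2 change of -3.32, Stmn1 fell 7.05-fold and the cyclin gene Ccnb2 fell 5.18-fold.

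**Figure D2:**
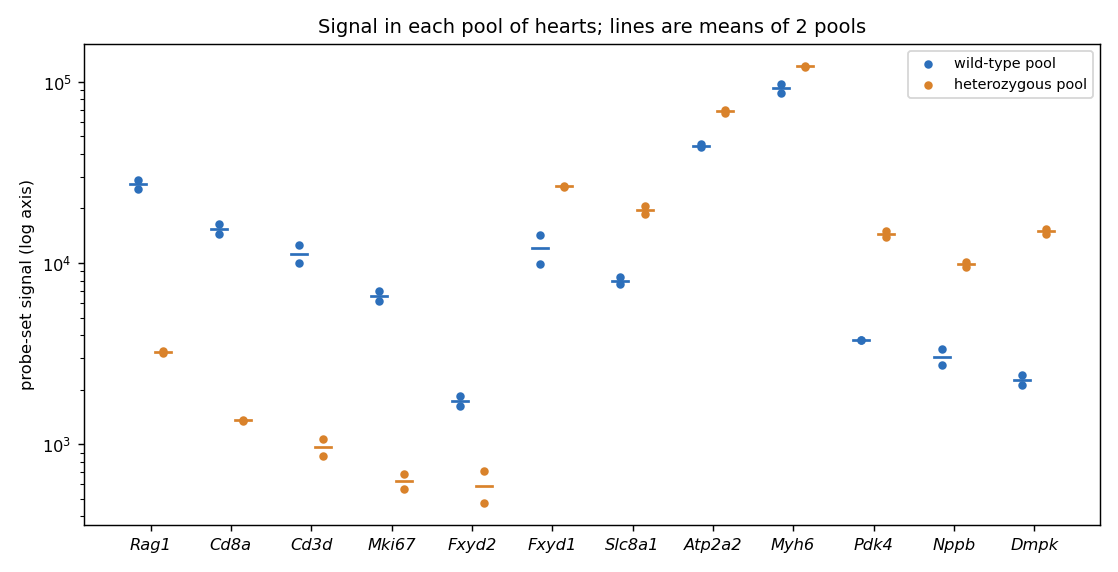
Probe-set signal (vertical axis, log scale) of 12 named genes in each wild-type pool (blue) and heterozygous pool (orange), with a line at the mean of 2 pools. Rag1, Cd8a, Cd3d, Mki67 and Fxyd2 lay lower and the other 7 genes higher in both heterozygous pools than in both wild-type pools; the order of Myh6 turned under cyclic loess (log2 change -0.036), and with arrays centred on the sarcomere list, the order of Myh6 turned and the means of Atp2a2 turned (log2 change -0.052).

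Beside the lymphocyte and thymus markers (median log2 change -2.42) and the cell cycle genes (-2.49), 4 further lists fell. In the interferon response list 14 of 22 tested genes fell, 17 when adjusted over the list alone, and none rose (median log2 change -0.85, camera adjusted p = 5.9e-07, and adjusted p = 0.158 with an estimated correlation). Psmb8 and Psmb9, subunits of the immunoproteasome that are also members of the proteasome list, fell 4.57-fold and 4.82-fold, Tap2, a peptide transporter, fell 3.61-fold, and Irf8, a transcription factor of blood cells, fell 3.45-fold. Of 30 tested proteasome and ubiquitin genes, 9 fell (8 when adjusted over the list alone) and 21 did not pass, with a median log2 change of -0.25 (camera adjusted p = 0.00619, and adjusted p = 0.240 with an estimated correlation). Cytosolic ribosomal protein genes fell in 12 of 21 cases, also when adjusted over the list alone (median log2 change -0.43, camera adjusted p = 9.2e-04, and adjusted p = 0.163 with an estimated correlation). Rpl13a fell 3.19-fold, Rps19 fell 2.37-fold and Rpl10a fell 1.90-fold. In the apoptosis list 10 of 26 genes fell and 2 rose, over all genes and over the list alone (median log2 change -0.42, camera adjusted p = 0.0101, and adjusted p = 0.240 with an estimated correlation). The members that fell included Birc5, an inhibitor of apoptosis that also acts in cell division (5.42-fold), Bid (4.35-fold), Pdcd4 (3.20-fold) and the death receptor gene Fas (2.78-fold). The apoptosis call ended without wild-type pool 2 (median log2 change -0.27) and with the lowest 60% of probe sets left out (camera adjusted p = 0.176). Across alternatives other than the estimated correlation, the list's adjusted p ranged from 0.00443 to 0.176.

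Contractile genes were higher in the heterozygous pools on the deposited scale. Of 26 tested sarcomere genes, 20 rose and none fell (22 and 1 when adjusted over the list alone), with a median log2 change of 0.67, or 1.59-fold (camera adjusted p = 1.1e-07, and adjusted p = 0.158 with an estimated correlation). Ldb3, a Z-disc protein gene, rose 3.67-fold from 9568 ± 1439 to 34964 ± 2239 (SD, n = 2; log2 change 1.88, SE 0.15, adjusted p = 4.1e-05), Mybpc3, of cardiac myosin-binding protein C, rose 2.10-fold and Myom1 rose 1.84-fold. Ckm, of muscle creatine kinase, rose 1.93-fold on its brighter probe set, while the other had a log2 change of -0.08 (adjusted p = 0.854). Myh6, the main adult cardiac myosin heavy chain of the mouse, rose 1.32-fold (log2 change 0.40, SE 0.12, adjusted p = 0.0321), a call that ended without wild-type pool 2, heterozygous pool 1 or heterozygous pool 2 (log2 changes of 0.31, 0.39 and 0.41) and turned to -0.036 under cyclic loess. Myh7, the slower fetal isoform, had a log2 change of 0.44 (adjusted p = 0.0843) that passed without wild-type pool 1 (0.71), and Acta1, skeletal alpha-actin, had one of -0.43 (adjusted p = 0.0541) that passed as lower under quantile normalization (-0.58), cyclic loess (-0.72) and 5 other alternatives, among them without wild-type pool 2 (-0.55). These increases stood beside the decrease of the lymphocyte and thymus markers, 5.37-fold in the median. Centring arrays on the sarcomere list itself instead lowers the log2 change of every gene alike and puts that list near 0 by construction. With it, 8 of the 15 lists that were higher had a median below 0: those of sarcomere, calcium handling, glucose use, oxidative phosphorylation, extracellular matrix, oxidative stress, heat shock and smooth muscle.

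Calcium handling genes moved in both directions, with 11 of 17 tested members higher, 4 lower and 2 not passing, over all genes and over the list alone. Their median log2 change was 0.63 on the deposited scale (camera adjusted p = 0.0129, and adjusted p = 0.205 with an estimated correlation). Slc8a1, the sodium-calcium exchanger that works on the sodium gradient set by the pump, rose 2.45-fold from 7995 ± 494 to 19589 ± 1305 (SD, n = 2; log2 change 1.29, SE 0.14, adjusted p = 1.9e-04). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, rose 2.26-fold, S100a1 rose 2.16-fold and Cacna1c, the pore of the L-type calcium channel, rose 2.09-fold. The release channel gene Ryr2 rose 1.79-fold (log2 change 0.84, SE 0.16), a call that ended without heterozygous pool 2 (0.78). Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose 1.55-fold (log2 change 0.63, SE 0.12), a call that ended under cyclic loess (0.26) and without heterozygous pool 1 (0.61) or heterozygous pool 2 (0.66), and its value turned to -0.052 with arrays centred on the sarcomere list. Other sodium, potassium and chloride transport genes rose in 13 of 23 cases, 14 when adjusted over the list alone, and none fell (median log2 change 0.75, camera adjusted p = 1.4e-04, and adjusted p = 0.158 with an estimated correlation). Those with the smallest p beside Kcnk3 were Slc4a3, an anion exchanger (2.21-fold), Abcc9, a subunit of the ATP-sensitive potassium channel (1.98-fold), and Kcnh2, of the rapid delayed rectifier (1.96-fold). Lymphocyte and thymus markers moved the opposite way in these pools, with a median log2 change of -2.42.

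Most tested genes of energy metabolism rose. In the fatty acid list 25 of 30 genes rose, also over the list alone, and none fell (median log2 change 0.74, camera adjusted p = 2.1e-08, and adjusted p = 0.158 with an estimated correlation). Pdk4, the kinase that holds back pyruvate oxidation, rose 3.86-fold from 3757 ± 20.1 to 14512 ± 737 (SD, n = 2; log2 change 1.95, SE 0.14, adjusted p = 2.3e-05), and Crat, Eci1 and Ech1 of fatty acid oxidation rose 2.44-fold, 2.22-fold and 1.86-fold. Oxidative phosphorylation genes rose in 37 of 54 cases and none fell (42 and 1 over the list alone), with a median log2 change of 0.55 (camera adjusted p = 2.8e-10, and adjusted p = 0.205 with an estimated correlation). Examples were Atp5j of the ATP synthase (2.46-fold) and Ndufb9 of complex I (1.81-fold). Of 19 citrate cycle genes 16 rose, 17 over the list alone, and none fell (median log2 change 0.74, camera adjusted p = 1.4e-06, and adjusted p = 0.186 with an estimated correlation). Ogdh rose 2.65-fold and citrate synthase, Cs, rose 1.99-fold. Glucose use genes rose in 17 of 21 cases and 1 fell, over all genes and over the list alone (median log2 change 0.66, camera adjusted p = 1.2e-05, and adjusted p = 0.205 with an estimated correlation). Gys1, glycogen synthase of muscle, rose 2.70-fold, Pygm, muscle glycogen phosphorylase, rose 2.38-fold and Slc2a4, the insulin-responsive glucose transporter, rose 2.33-fold. The median of the lymphocyte and thymus markers was 5.37-fold lower in the same pools.

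In the list of hypertrophy and fetal program genes, 13 of 18 rose and 1 fell (14 and 2 when adjusted over the list alone; median log2 change 0.86, camera adjusted p = 4.4e-05, and adjusted p = 0.158 with an estimated correlation). Nppb, which encodes B-type natriuretic peptide, rose 3.23-fold from 3048 ± 430 to 9811 ± 361 (SD, n = 2; log2 change 1.69, SE 0.16, adjusted p = 9.4e-05). Nppa, of atrial natriuretic peptide, rose 1.37-fold (log2 change 0.46, SE 0.15, adjusted p = 0.0403), a call that ended without wild-type pool 2, heterozygous pool 1 or heterozygous pool 2 (log2 changes of 0.31, 0.38 and 0.54), ended under quantile normalization (0.33) and cyclic loess (0.25), and turned to -0.23 with arrays centred on the sarcomere list. Xirp1, an intercalated disc gene, rose 4.49-fold, Ccn2, a matrix growth factor, rose 2.76-fold and Nkx2-5, a cardiac transcription factor, rose 2.31-fold. Myh7 (log2 change 0.44, limma adjusted p = 0.0843) and Acta1 (-0.43, limma adjusted p = 0.0541), also members of this list, did not pass over all tested probe sets. Extracellular matrix genes rose in 18 of 30 cases, 20 over the list alone, and none fell (median log2 change 0.68, camera adjusted p = 1.1e-05, and adjusted p = 0.158 with an estimated correlation). Among them were Timp3 (log2 change 1.32), Col4a2 (2.14-fold) and Mgp (2.05-fold). Oxidative stress genes rose in 15 of 32 cases and 1 fell (16 and 1 over the list alone; median log2 change 0.45, camera adjusted p = 0.00169, and adjusted p = 0.163 with an estimated correlation). Gpx3 rose 2.49-fold and the metallothionein Mt1 rose 2.47-fold. Of 27 heat shock genes 9 rose and 4 fell (10 and 4 over the list alone; median log2 change 0.35, camera adjusted p = 0.0477, and adjusted p = 0.240 with an estimated correlation). Herpud1 rose 1.95-fold and the small heat shock protein gene Hspb8 rose 1.90-fold. The heat shock call ended under quantile normalization (camera adjusted p = 0.166) and cyclic loess (0.180). It also ended without wild-type pool 1, heterozygous pool 1 or heterozygous pool 2 (median log2 changes of 0.13, 0.44 and 0.24). Further alternatives that ended it were fry, no filter, the lowest 60% left out, moderation without a trend and centring on the sarcomere list. Across alternatives other than the estimated correlation, the list's adjusted p ranged from 0.0160 to 0.180. Beside these lists the lymphocyte and thymus markers fell, at a median log2 change of -2.42.

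Markers of endothelium, fibroblast and atrium rose, against the fall of the lymphocyte and thymus markers (median log2 change -2.42). Endothelial markers rose in 10 of 14 cases, 11 over the list alone, and none fell (median log2 change 0.88, camera adjusted p = 7.9e-05, and adjusted p = 0.158 with an estimated correlation). Cdh5, the cadherin of endothelial junctions, rose 2.17-fold and the water channel gene Aqp1 rose 2.12-fold. Of 15 fibroblast markers 11 rose and 1, Thy1, which is also a T cell gene, fell, over all genes and over the list alone (median log2 change 0.75, camera adjusted p = 0.00272, and adjusted p = 0.184 with an estimated correlation). Gsn rose 1.94-fold, Dcn 1.86-fold and Col1a1 2.27-fold, although the other Col1a1 probe set had a log2 change of -0.05 (adjusted p = 0.814). Atrial and vessel markers rose in 6 of 7 cases, also over the list alone (median log2 change 0.82, camera adjusted p = 0.00297, and adjusted p = 0.205 with an estimated correlation). The atrial myosin light chain gene Myl7 rose 1.79-fold and Kcna5 rose 2.66-fold. Among 10 smooth muscle and pericyte markers 3 rose, also over the list alone, and 7 did not pass (median log2 change 0.51, camera adjusted p = 0.0430, and adjusted p = 0.240 with an estimated correlation). This list call ended without wild-type pool 2 or heterozygous pool 2 (median log2 changes of 0.45 and 0.44). It also ended with the lowest 60% of probe sets left out (camera adjusted p = 0.179). Across alternatives other than the estimated correlation, the list's adjusted p ranged from 0.0134 to 0.179. The 3 tested lung markers rose: Sftpc, Ager (2.75-fold; without heterozygous pool 1 a log2 change of 1.00, a call that ended) and the secretoglobin Scgb1a1, which reached a signal of 48574 ± 5269 from 19507 ± 2218 (SD, n = 2; 2.49-fold). Of 4 tested nerve markers Mbp, of myelin, fell (log2 change -1.32, but -0.089 on its other tested probe set), 1 rose and 2 did not pass.

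The remaining lists did not pass camera; those of skeletal muscle, adipose, erythroid and adrenergic genes passed fry, and those of skeletal muscle and erythroid genes also passed camera on the mean of a gene's probe sets. Among 14 skeletal muscle markers 3 rose and 6 fell (3 and 8 over the list alone; median log2 change -0.68, camera adjusted p = 0.0984, and adjusted p = 0.248 with an estimated correlation). On the mean of probe sets the median was -0.93 (adjusted p = 0.0185; range across alternatives 0.0116 to 0.280). Actn3, the fast-fibre actinin, fell 6.11-fold and parvalbumin, Pvalb, fell 2.43-fold. Adipose markers gave 0 rises and 4 falls among 16 genes, also over the list alone (adjusted p = 0.219, and adjusted p = 0.372 with an estimated correlation). The lipogenic enzyme genes Acly and Fasn fell 2.83-fold and 2.14-fold. Macrophage and myeloid markers rose in 2 and fell in 6 of 17 cases, also over the list alone (adjusted p = 0.274, and adjusted p = 0.565 with an estimated correlation). Ctss fell 2.18-fold and Cd74, the invariant chain, fell 1.98-fold. Erythroid markers rose in 3 of 6 cases, also over the list alone (adjusted p = 0.0531, and adjusted p = 0.240 with an estimated correlation). Alas2 of heme synthesis rose 1.86-fold. The erythroid list passed without wild-type pool 1 (median log2 change 0.47) and with the pool number as a block (camera adjusted p = 0.0459). Its adjusted p ranged from 0.00842 to 0.442 across alternatives. Adrenergic and cyclic AMP genes rose in 6 and fell in 1 of 20 cases, also over the list alone (adjusted p = 0.0932, and adjusted p = 0.240 with an estimated correlation). Prkaca, the catalytic subunit of protein kinase A, rose 2.60-fold. Of 32 genes of Src, Ras and MAP kinase signalling 6 rose and 5 fell, also over the list alone (adjusted p = 0.350, and adjusted p = 0.416 with an estimated correlation). Mapkapk2 rose 2.64-fold and Map3k1 fell 2.57-fold. Immediate early genes rose in 6 and fell in 6 of 22 cases, also over the list alone (adjusted p = 0.778, and adjusted p = 0.857 with an estimated correlation). Jun rose 2.95-fold and Egr2 fell 2.79-fold. Markers of lymphocyte and thymus fell beside all of these lists (median log2 change -2.42).

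**Figure D3:**
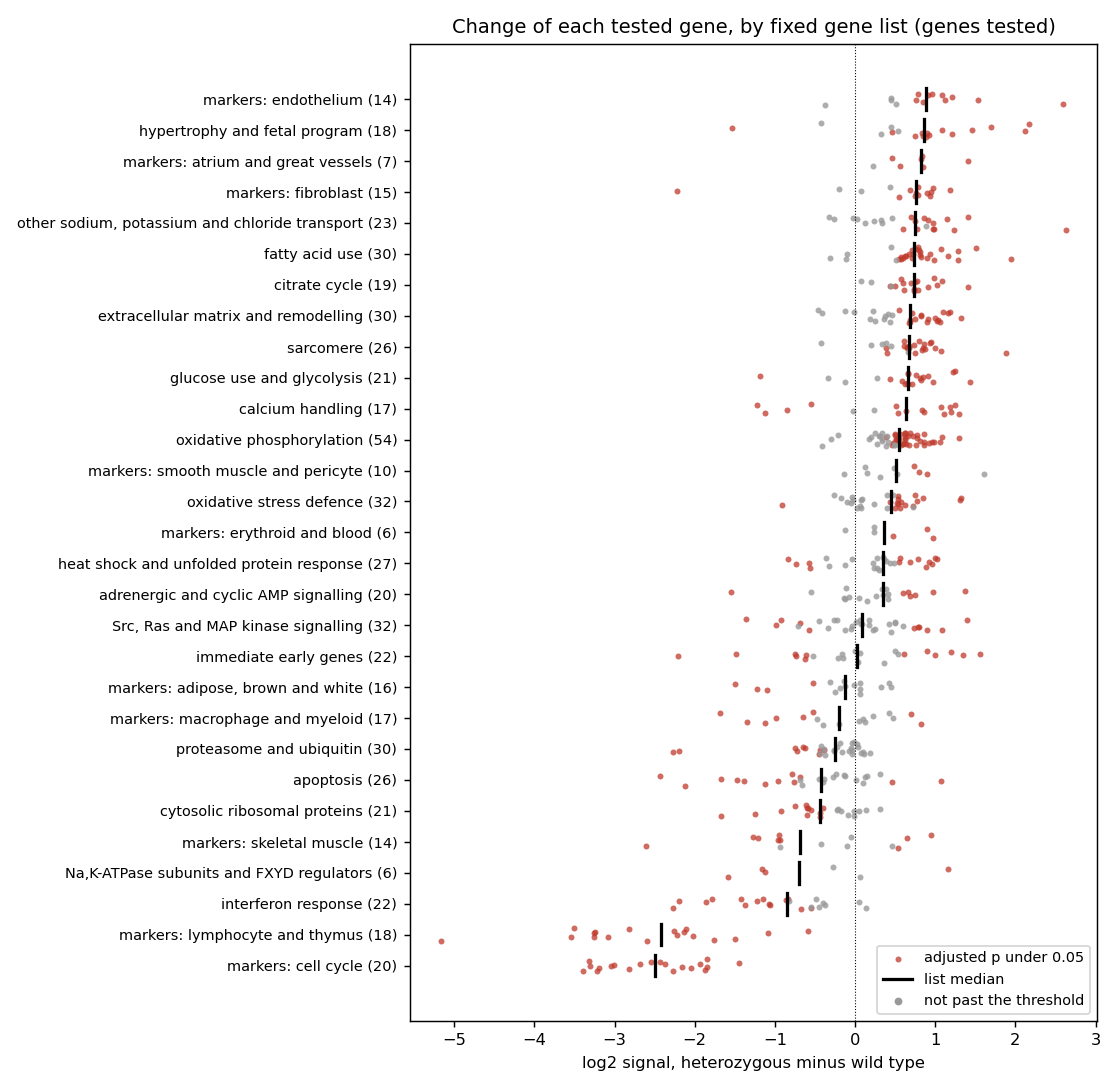
Log2 change of every tested gene (horizontal axis, heterozygous minus wild type, 1 point per gene) in the 29 tested lists, ordered by median (black bar), with the number of tested genes in brackets and genes past an adjusted p of 0.05 in red. Lists of heart muscle and metabolism lie to the right, with medians from 0.55 to 0.86 on the deposited scale, and the cell cycle and lymphocyte lists lie at -2.49 and -2.42; with arrays centred on the sarcomere list, 8 of the 15 higher lists have medians below 0.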

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

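The probe sets described here were picked after their values were seen, as members of the fixed lists that were too dim to be tested, with a mean signal of at least 200 in the heterozygous pools and at least 2-fold above the wild-type pools; they were 7 of the 99 probe sets of the 80 list genes with no tested probe set. No test was made of them, and folds are ratios of mean signals.

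Cacna1g, of a T-type calcium channel, was 5.13-fold higher in the heterozygous pools (286 ± 20.7 against 55.8 ± 13.1, SD, n = 2). Adgre1, which encodes the macrophage protein F4/80, was 3.98-fold higher (264 ± 35.1 against 66.5 ± 5.02), while the tested macrophage list did not pass camera or fry. Cideb was 3.04-fold higher, with a wide spread (253 ± 142 against 83.2 ± 23.3). Atp1b2, the beta 2 subunit of Na,K-ATPase, was 2.46-fold higher (204 ± 16.8 against 82.8 ± 10.7). Sftpd, of surfactant protein D, was 2.28-fold higher, like the 3 tested lung markers. The potassium channel gene Kcnd3 was 2.26-fold higher and the chloride channel gene Clcn2 was 2.24-fold higher.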

How the results depend on the processing

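The scaling to a common sarcomere mean was chosen after the result was seen; every other alternative was planned. Of 2856 calls, 2587 were kept under quantile normalization, 2503 with a common median and 2547 under cyclic loess, with 0 in the opposite direction. Without the filter on dim probe sets, which also changes the trend the spread is shrunk to, the calls numbered 1206 (482 higher, 724 lower), of which 1053 were shared; the cause was not tested. Leaving out each pool in turn, with the lone pool assumed to vary like the other group, gave 1781 to 2246 calls (653 to 1126 higher, 1120 to 1147 lower) and 19 to 21 passing lists; fewer samples account for part of this, and without heterozygous pool 1 or 2 the totals were 1806 and 1781. Centring on the sarcomere list gave 4351 calls (171 higher, 4180 lower). It shifts each array by its own constant, which lowered the log2 change of every probe set by the same amount. Myh6 turned to -0.29, Nppa to -0.23, Bpgm to -0.21, Pmp22 to -0.13 and Atp2a2 to -0.052. With this centring 20 lists passed, as camera compares a list with the other genes. Cyclic loess turned Myh6 to -0.036, and the cause was not tested. With an estimated correlation 0 lists passed, with 2 residual degrees of freedom, while fry, which asks only whether genes of a list move together, passed 25. Over 2216 comparisons of 140 named probe sets with alternatives, 138 calls ended, 16 were gained and 6 values reversed. Of 135 calls, 67 held under every alternative in which their probe set was tested. Some of these probe sets were filtered out in some alternatives. Among 551 such comparisons of lists, 36 calls ended, 21 of them with the estimated correlation, and 9 were gained. The pool number as a block gave 3035 calls and 22 passing lists; deviations of same-numbered pools correlated at 0.158, with 2 pairs, too few to show whether the numbers stand for a shared batch. Signal limits what can be seen: below a mean of 349 no probe set was tested.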

Other observations

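The 9 lists used here were drawn up after the main results were seen; 12 of 20 thymocyte genes, 7 of 17 B cell genes and 9 of 30 glucocorticoid response genes, but none of the thymic epithelium, clock, intercalated disc or autophagy genes, were also in a fixed list. The tests on thymic epithelium and on other splits of the pools, the centring on the sarcomere list, the estimate of tissue shares and the added conditions on the glucocorticoid and scaling tests were chosen only after the result was seen.

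Of 19 tested genes of intercalated disc and adhesion 13 rose in the heterozygous pools and none fell (median log2 change 0.67, camera adjusted p = 2.2e-06, and adjusted p = 0.103 with an estimated correlation). Jup, which encodes plakoglobin, had a log2 change of 1.72 (SE 0.16), Sspn of 1.39, the cadherin gene Cdh2 of 1.38 and Gja1, the main gap junction gene of ventricle, of 0.56. Of 10 potassium channel genes 6 rose and none fell (median log2 change 0.76, camera adjusted p = 0.00799, and adjusted p = 0.169 with an estimated correlation), and 17 of the 21 genes of that list were also in a fixed list. In the autophagy and lysosome list 8 of 20 genes rose and 2 fell (median log2 change 0.45, camera adjusted p = 0.0160, and adjusted p = 0.169 with an estimated correlation). Map1lc3a stood at 1.36 and the cathepsin gene Ctsl at -1.40. The list's median lay at only the 89.45 percentile of 10000 random lists matched on mean signal, whose median was 0.22. Fast skeletal muscle genes rose in 6 and fell in 6 of 18 cases (median log2 change -0.08, camera adjusted p = 0.748, and adjusted p = 0.817 with an estimated correlation), and all 20 genes of that list were also in a fixed list. Casq1 (0.54), Myl1, Aldoa, Eno3, Ckm and Pgam2 (0.97) rose. Tnnc2 (-0.93), Atp2a1, Myh1, Tnnt3, Pvalb and Actn3 (-2.61) fell, so the median near 0 describes neither set. Beside these medians, that of the sarcomere genes was 0.67 and that of the lymphocyte and thymus markers -2.42.

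Clock genes moved in opposite directions. Arntl, the activating partner of the clock, had a log2 change of -1.87 (SE 0.21, adjusted p = 2.9e-04), while Per1 (1.77), Per2 (1.18), Nr1d1 (1.02), Nr1d2 (0.89) and Bhlhe40 (0.82) rose. Tef rose 2.07-fold, and Dbp had a log2 change of 0.46 (adjusted p = 0.0554). Of 13 tested clock genes 6 rose, 1 fell and 6 did not pass (camera adjusted p = 0.0347, and adjusted p = 0.203 with an estimated correlation). The mean log2 signal of Tef, Dbp, Nr1d1 and Per2 minus that of Arntl was -0.30 and -0.24 in the wild-type pools and 2.57 and 2.48 in the heterozygous pools.

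Lymphocyte, thymus and cell cycle genes were lower in the heterozygous pools. Against blood or lymph node as the source of the wild-type signal, B cell genes changed less than thymocyte genes, on the brightest probe set of each gene. Of 12 B cell genes, 8 were lower and 4 did not pass (median log2 change -1.03), while all 15 thymocyte genes were lower (-3.25). The difference was 2.22 (permutation test, p = 6e-05, 100000 permutations, two-sided). The test shuffled genes between the lists. Genes are not independent replicates, so its p-value does not measure the spread between pools. Ighm entered the B cell list with a log2 change of -1.09, while its other tested probe sets had changes from -1.60 to -4.92. The size of the difference therefore depends on the probe sets taken, and the test was not run with others. Thymus tissue in the wild-type pools is a candidate explanation: genes known from thymic epithelium had a median log2 change of -1.56, with 8 of 10 lower and Ccl25 going from 7651 to 761.4 and Ly75 from 3164 to 279.3, though Krt8, Krt18, Ctsl and Ly75 are made by other cells too. Rag1 stood at the 97.6 and 98.2 percentile of tested signals in the wild-type pools and still at 76.1 and 76.4 in the heterozygous pools. An estimate of tissue shares took thymocyte genes as coming from thymus alone and sarcomere genes from heart alone. It also took these tissues as the only sources, signal as proportional to RNA, and genotype as without effect on these genes. The median changes would then put thymus at 39.7% of the RNA in the wild-type and 4.18% in the heterozygous pools. Decreases of single thymocyte genes ran from 2.13-fold (Cd1d1) to 35.8-fold (Cd8b1), so these shares are rough. As both wild-type pools carry the signal, no count without them can be had, and an effect of genotype on the thymus, age within the range given and dissection remain open and untested.

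Heart muscle and metabolic lists were higher in the heterozygous pools. The change of the 150 tested genes of 5 heart lists did not follow mean signal (Spearman's rho 0.0037 across genes, which are not independent replicates). This leaves little room for a compression that grows steadily with signal. It cannot exclude compression of only the few brightest genes, since rho sees only a steady trend. The authors' scaling of each array stays open: all 15 list calls were kept under 3 other scalings, but camera cannot see a constant shift of an array, so this does not decide. A lower share of heart RNA in the wild-type pools may account for a common rise. As the whole cause it cannot be told apart from an effect of genotype. Of the 1110 genes called higher, 96 (8.65%) passed a test for a change above the sarcomere median of 0.67 (adjusted p under 0.05). That share lay between the bounds of 5% and 10% set beforehand. By the same kind of test, 25 exceeded the upper quartile of the sarcomere genes (0.85). Genes that lay above these values without passing the test are not counted. Those 96 include Dmpk, 2.05 above the median on the log2 scale (adjusted p = 1.3e-04), Kcnk3 (1.96), Pdk4 (1.28), Ldb3 (1.21) and Nppb (1.02), but also the lung markers Sftpc (1.58) and Scgb1a1 (0.65), so lying above the median does not mark a gene as answering to genotype.

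Increases beyond the sarcomere shift were set against hormone and time of day. The glucocorticoid response list passed the bound set beforehand, at the 99.2 percentile of 10000 random lists matched on mean signal (camera adjusted p = 0.00298, and adjusted p = 0.203 with an estimated correlation). However, the intercalated disc list (99.85) and the potassium channel list (99.93) scored as high. The glucocorticoid list's median of 0.44 lay below the sarcomere shift of 0.67, and 7 of its 22 genes lay above that shift, so the test could not single out the hormone. Its member Fkbp5 fell (-1.31), but a fall of Fkbp5 along with thymus RNA is not excluded. A different clock time of heart removal is consistent with the clock genes: those with opposite daily peaks moved apart by 2.80. That value rests on Arntl alone on its side, as Npas2 was not tested, Clock (0.34), Cry1 and Nfil3 did not pass, and a fall of Arntl along with thymus RNA (lymphocyte and thymus median -2.42) is not excluded. It also leaves open how much of the other increases would follow the clock, since of the clock genes only Per1 is among the 96, and an effect of genotype on the clock is equally open.

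The Dmpk neighbours Six5 and Dmwd, on either side in the gene order of the mouse assembly GRCm38.p6, both rose with it. Six5 had a log2 change of 2.81 from a dim wild-type signal (mean 95.1). Dmwd had one of 0.80 (SE 0.27, limma adjusted p = 0.0415), close to the sarcomere median of 0.67. Of the 3 ways to split the 4 pools evenly, 1, the real one, gave 2856 calls by limma. The highest of the others gave 0 (24 at an unadjusted p under 0.05). Every other split puts 1 pool of each genotype in both groups. The genotype difference then adds to the spread within groups, so few calls follow by construction and the contrast decides nothing. With 3 splits no share under 0.05 can be reached either. For B cell genes the list test gave a camera adjusted p of 1.4e-04 (0.149 with an estimated correlation), for thymic epithelium 2.2e-06 and for thymocytes 2.2e-14 (both 0.103 with an estimated correlation).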
